A study of Homo sapiens with 42 samples.

How the data were processed

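The arrays were Exiqon miRCURY LNA arrays, version 9.2, read by a GenePix scanner and exported with GenePix Pro 6.1.0.4, per the file headers, with probe names from miRBase 11.0. The deposited scanner files give each spot's intensity, unnormalized per the file headers, in a green channel that carries the Hy3 dye named in the labels, together with its local background and the percent of saturated pixels. A red channel, for which the labels name no dye, stayed at a median of 39 to 47 units on every array and was not used. RNA was extracted with a kit that keeps small and long RNA, per the labels. The authors' series matrix holds 685 of the array's probes, among them all 568 human ones, as linear intensity values that include negative numbers; its scale and centring are not stated. Column medians of that matrix ran from −65.3 to 137. Column maxima were alike on most arrays of batches 1 to 3 and on 4 of the 8 arrays of batch 5, and differed on the others, so how the authors scaled the values stays open. The matrix served as an alternative, as log2 of the value, set to 0 where negative, plus 50.

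Each array held 9792 spots and 2246 probe identifiers on 1 of 2 spot maps, an early slide lot (19 arrays) and a late one (23 arrays), which differ at 212 spots; spots were joined by probe identifier. Batches were taken from the labels for the control arrays. The others were placed with the control array whose scan name holds the same date string. For 1 array with a date string of its own, the nearest scan day of the headers was used. Donors were renumbered from 1 to 13, and replicates are named by these numbers. Names are the array's own, which are old; 337 of the 568 human probes matched a miRNA gene of the RefSeq annotation of GRCh38.p14, used for names and neighbours. There miR-143 and miR-145, miR-221 and miR-222, miR-141 and miR-200c, miR-200a and each of miR-200b and miR-429, miR-144 and miR-451, miR-199a and miR-214, and miR-17 and each of miR-19a and miR-20a lie within 10000 bases of each other. No genome build is named for the probes, so positions are not given.

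Green median intensities were background corrected with normexp (offset 50), the 13 control identifiers were left out, the log2 values of the spots of a probe were averaged, and these means were quantile normalized between arrays over all remaining probes. A human probe was tested where its foreground exceeded the local background by 2 background SDs in at least a share of 0.5 of its spots on a share of 0.5 of the arrays of a compared group. This left 564 probes in TE versus TNE and 568 in the others. No probe was saturated on every array of a group, and 2 were not above background on any S array.

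Tests used limma 3.58.1 in R 4.3.3 (statmod 1.5.0), and tables and figures Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05, and are two-sided. TE and TNE were compared within 10 donors with the donor as a fixed block, since the design text pairs them by number; the control donor entered with the TNE array of batch 2. Deviations of TE and TNE of one donor from their group means correlated at 0.27 to 0.68 (median 0.47), over 0.1 in 10 of 10, against a median of −0.19 between donors. The best partner was the own one in 6 of 10 pairs. The arrays of a pair also shared a batch, so these values cannot tell a shared donor from a shared batch. TS was compared with TNE and TE in one fit of batches 1 to 3 with batch fixed and donor as a random block (correlation 0.134). S was compared with the others in one fit of all 42 arrays with batch and donor fixed and the control RNA as a group of its own, which left 20 residual degrees of freedom. Counts of S arrays on one side were taken after subtracting the control array of the batch, and of TS arrays against the mean of the other group in the batch.

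The naming rule, fixed before the data were examined, took per comparison up to 12 probes in each direction with the largest difference among those past the threshold, or the 10 smallest p where fewer than 5 passed, plus members of 24 fixed lists. These are 18 miRNA families and clusters and marker lists of leukocytes, erythroid, endothelial, muscle, neural and liver cells, each as named in the results. Lists with at least 3 tested probes were tested with camera (correlation preset at 0.01, and estimated), and with fry, adjusted over the lists of a comparison. Camera compares a list's probes with the other probes. With the preset correlation 29 of 132 list tests passed, and with the estimated correlation 9. Several lists share probes with others.

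Each fit was tested on simulated data with 100 changed probes. A log2 change of 1 was recovered in 99% of them for TE versus TNE, 97% for TS versus TNE and 77% for S versus TNE, and a change of 2 in 100%, 100% and 95%. Between 0.99% and 7.4% of the calls were wrong. The changed probes were drawn at random and the simulated noise was independent between arrays. These shares therefore do not hold for probes with a larger spread. Alternatives fixed beforehand were no background correction, median scaling, no filter on dim probes, the authors' matrix, leaving out a TNE array whose title carries an unexplained suffix, fits with and without the donor block or batch, subtracting the control arrays, and leaving out each replicate in turn. Chosen after seeing the data were mean pixel intensity, a background taken from the plant probes, a filter against the 95th percentile of the plant probes, and leaving out the 2 weakest S arrays. A log ratio to the second channel was not run, because that channel stayed at its floor and the labels name no reference RNA.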

Results

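Total RNA from human prostate tumor biopsies was hybridised to 42 single-colour arrays that carry locked nucleic acid probes, a chemistry that strengthens short duplexes such as a probe with a microRNA (miRNA). The labels sort the samples into tumor normal epithelial cells (TNE), tumor epithelial cells (TE), tumor stem cells (TS) and stromal cells (S). How the cells were separated is not given in the sources used here. The samples came from 13 donors, of whom 11 gave TNE, 11 gave TE, 4 gave TS and 11 gave S. Both TE and TNE came from 10 donors, S and TNE from 11, S and TE from 10, and TS and TE from 3. TNE RNA of 1 donor was run again in every batch as a control, so TNE holds 16 arrays. TE, TNE and TS were hybridised in batches 1 to 3 and S in batches 5 and 6. Normal prostate groups that the labelling key also names were not analysed here.

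Each of the 568 human probes was printed in 4 spots. The median raw foreground intensity of an array lay between 281 and 595 scanner units. The share of human probes above local background had a median of 98.1% on TE arrays, 97.1% on TNE, 99.6% on TS and 85.4% on S, and the S arrays ranged from 23.8% to 98.1%. This standard was weak, because probes for plant miRNAs passed it too. On S replicate 13, the array at 23.8%, 5132 of 9792 spots were flagged as not found and 437 as bad. Spots flagged as bad were left out of the probe means on every array, and spots flagged as not found were kept. In every group at least 391 of the 568 human probes exceeded the 95th percentile of the 395 plant probes on no array. Differences at such levels are those of the fitted intensities and do not give the size of the change in the miRNA. S replicate 10 had the lowest 95th percentile of human probe intensity after background subtraction, 558.5 units, against a median of 2351 over S and 4247 over TE. Its median raw foreground was high, at 591 units, over a median background of 253 units. After background subtraction its 75th percentile was 445 units, so its bright and dim human probes lay close together. In the authors' matrix its maximum was 3011, against 22058 to 85341 on the other S arrays of batch 6. Its values therefore carry little of the difference between probes. The number of arrays limits the precision of every value below, and all levels are log2 normalized intensities.

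The control TNE RNA gave a median SD per probe of 0.193 over its 6 arrays. The arrays of batches 2 and 4 carried the same slide identifier, and their spot residuals correlated at r = 0.635, against at most 0.181 between other control arrays of one slide lot. Counted as 1 sample, they left a median SD of 0.174 (n = 5). The SD between the 10 other TNE donors had a median of 0.165, so on these values 1 RNA varied between batches about as much as TNE arrays varied between donors. Those donors' arrays also lay in several batches, so their SD holds technical spread as well, and the 2 cannot be separated. Under median scaling the control RNA's median SD was 0.428 against 0.467 between donors, and with the authors' matrix values 0.349 against 0.498.

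The paired comparison of TE with TNE asked how tumor epithelium differed from epithelium labelled normal in the same donors. TE held more of several single miRNAs known from other cell types. miR-451, abundant in red blood cells, was higher (log2 difference 2.99, SE 0.47, n = 10 pairs, adjusted p = 0.00049), at 10.85 ± 1.63 (SD) in TE against 7.87 ± 0.19 in TNE. The endothelial miR-126 was higher by 1.48 (SE 0.29) and miR-143, known from smooth muscle and other mesenchymal cells, by 1.48 (SE 0.33). The TNE levels of these 3 exceeded the 95th percentile of the plant probes on 0 of 10 arrays. Of the miRNAs known from epithelium, miR-31 fell by 2.19 (SE 0.24) and miR-205, abundant in basal epithelial cells, by 1.90 (SE 0.28), from 12.25 ± 0.23 to 10.35 ± 1.04. miR-222 fell by 1.89 (SE 0.22) and miR-221 by 1.34 (SE 0.14). All 7 moved the same way in 10 of 10 pairs.

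In all, 25.9% of 564 probes passed, 54 higher and 92 lower in TE, and 34.6% had an unadjusted p under 0.05. Other probes that rose included miR-765 (2.01, SE 0.30), miR-483-5p (1.96, SE 0.17), encoded within the IGF2 gene, miR-665 (1.73, SE 0.24), miR-583 (1.53, SE 0.18), miR-671-5p (1.33, SE 0.16), miR-658 (1.26, SE 0.13), miR-185 (1.13, SE 0.16), miR-518c* (1.13, SE 0.11) and miR-518f* (1.08, SE 0.11). For miR-518f* no TE or TNE array exceeded the 95th percentile of the plant probes. Among those that fell were miR-31* (−1.74, SE 0.16), miR-130a (−1.43, SE 0.15), miR-27a (−1.38, SE 0.19), miR-886-3p (−1.36, SE 0.16), miR-27b (−1.26, SE 0.17), miR-20a (−1.22, SE 0.15), miR-106a (−1.20, SE 0.15) and miR-138 (−1.16, SE 0.22). miR-138 was lower in 9 of 10 pairs, and the others moved one way in 10 of 10. Probes for plant miRNAs moved beside these: 54 of 395 (13.7%) were called higher and 24 lower in the same test. The plant probes called higher had a median difference of 0.49 and a largest of 2.03, against 0.57 and 2.99 for the human ones. Of the human rises named here, only that of miR-451 exceeded the largest plant rise. For probes called lower the median and largest were −0.32 and −1.66 in plant probes and −0.55 and −2.19 in human ones.

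The miR-221/miR-222 list, repressors of the cell cycle inhibitor CDKN1B, fell in 3 of 3 probes, also 3 when adjusted over the list alone (camera adjusted p = 0.00705; adjusted p = 0.445 with an estimated correlation). The miR-23/miR-24/miR-27 clusters fell in 6 of 7 probes, also 6 when adjusted over the list alone (camera adjusted p = 0.000643; adjusted p = 0.445 with an estimated correlation). In the MYC-driven 17-92 and paralog clusters, 12 of 23 probes fell, with miR-17 at −1.14 (SE 0.15) and miR-19a at −1.01 (SE 0.14), while miR-363 rose by 0.80 (SE 0.12). Over that list alone the counts were again 12 and 1 (camera adjusted p = 0.00303; adjusted p = 0.55 with an estimated correlation). No other list passed camera in this comparison. Fry, which asks whether the probes of a list move one way and does not set them against other probes, called these 3 and 10 more: lower, other epithelial (adjusted p = 0.00016), miR-181 (0.000109), miR-15/miR-16 (0.0205), miR-34/miR-449 (0.0211), prostate-cited (0.0333), miR-30 (0.035) and miR-200 (0.0381); higher, erythroid (0.0059), miR-143/miR-145 (0.0381) and miR-199/miR-214 (0.0495). Within batches 1, 2 and 3, the list medians were −1.54, −0.94 and −1.46 for miR-221/miR-222, −1.32, −0.54 and −1.10 for miR-23/miR-24/miR-27, and −0.26, −0.07 and −0.24 for 17-92.

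Among epithelial and tumor-related lists, none of which passed camera, single members did. In the miR-200 family, repressors of the ZEB transcription factors, miR-200a fell by 0.84 (SE 0.18) and miR-429 by 0.67 (SE 0.17), 2 of 9 probes and 4 when adjusted over the list alone. Of 10 other epithelial probes 3 fell and miR-96* rose (0.70, SE 0.13), with the same counts over the list alone. Of 19 probes often cited in prostate tumours 5 fell, among them miR-21 (−0.65, SE 0.18) and miR-32 (−0.42, SE 0.11), and 2 rose, miR-375 (0.77, SE 0.21) and miR-96*; the counts over the list alone were 6 and 2. The p53 target miR-34a fell by 1.16 (SE 0.18), 1 of 3 lower probes of the miR-34/miR-449 family, also 3 when adjusted over the list alone.

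Counts of probes lower and higher, with those adjusted over the list alone in brackets, were as follows for the remaining families: let-7, 3 and 1 of 15 (3 and 1), with let-7i at −0.81 (SE 0.12); miR-15/miR-16, 3 and 0 of 8 (3 and 0); miR-29, 2 and 0 of 6 (2 and 0); miR-30, 4 and 0 of 9 (4 and 0); miR-181, 2 and 0 of 6 (4 and 0). The miR-99/miR-100/miR-125 group had 0 lower and 2 higher of 10 (0 and 1), the 14q32 cluster 3 and 1 of 43 (3 and 1), and the embryonic stem cell clusters 1 and 1 of 11 (1 and 0). No probe of the miR-10 family's 3 passed either way.

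No marker list of other cell types passed camera, which tested neither the endothelial nor the liver list, and single members passed. Among 4 erythroid probes miR-451 passed, and 2 passed when adjusted over the list alone, with miR-144, its genomic neighbour, at 0.68 (SE 0.25, adjusted p = 0.064). The leukocyte markers miR-142-3p (0.77, SE 0.18) and miR-142-5p (0.74, SE 0.16) rose in 10 of 10 pairs and miR-146a fell by 0.55 (SE 0.11), 3 of 6 probes and the same 3 over the list alone. miR-126 was the 1 of 2 endothelial probes to pass, miR-143 the 1 of 9 muscle probes and miR-124 (0.22, SE 0.06) the 1 of 8 neural probes, unchanged over each list alone. The miR-143/miR-145 cluster rose in 1 of 4 probes (2 over the list alone), the miR-199/miR-214 cluster in 1 of 6, miR-214 (0.50, SE 0.14), also 1 over the list alone. miR-122, the liver marker, differed by 0.0025 (SE 0.04, adjusted p = 0.974).

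All 54 probes called higher were higher in the mean of the pairs of each of the 3 batches, and of the 92 called lower 92, 92 and 91 were lower in batches 1, 2 and 3. Directions near 0 depend on the scaling: median scaling put the median difference of all probes at 0.29, split its 117 calls 88 higher to 29 lower, and turned the medians of the 17-92, 14q32, miR-15/miR-16, miR-29, miR-30, miR-34/miR-449, miR-181, let-7, embryonic, prostate-cited and other epithelial lists above 0.

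**Figure D1:**
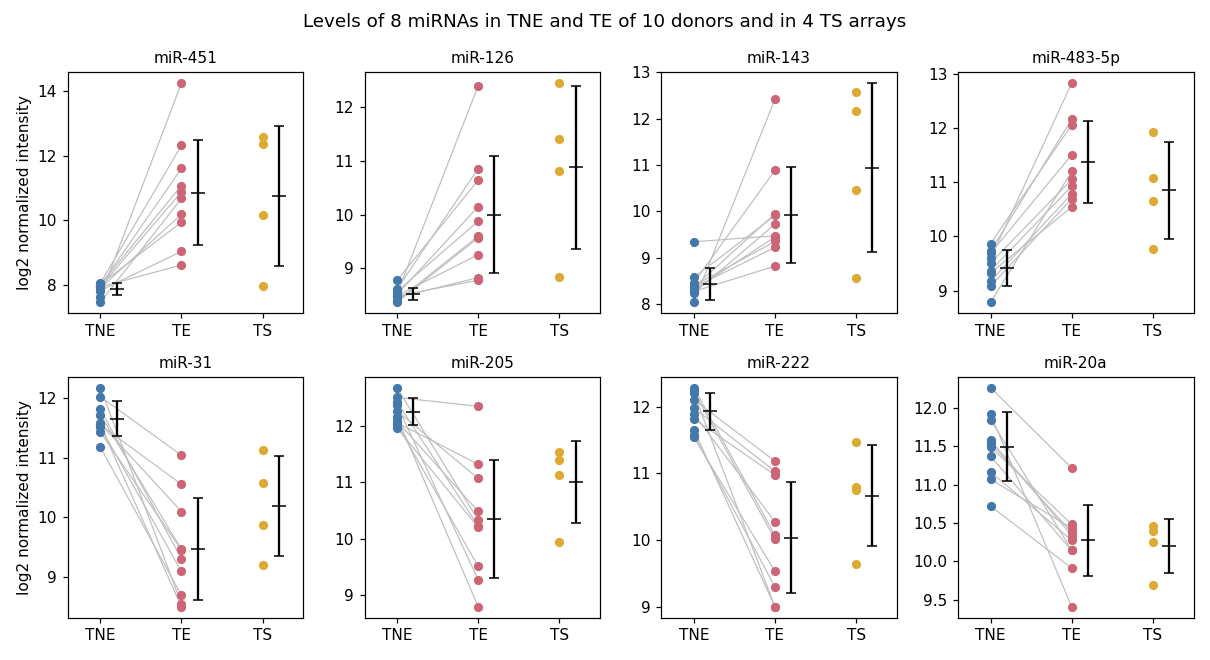
Log2 normalized intensity (vertical axes) of 8 miRNAs in TNE and TE of 10 donors, with grey lines joining the arrays of a donor, and in the 4 TS arrays. Points are arrays and the black bars beside them are the mean ± SD; miR-451, miR-126, miR-143 and miR-483-5p were higher in TE than in TNE in 10 of 10 pairs, miR-31, miR-205, miR-222 and miR-20a were lower in 10 of 10, and the TS arrays spread widely on miR-451 (10.76 ± 2.17).

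Against TNE, the 4 TS arrays were higher in miR-451 by 2.48 (SE 0.72, adjusted p = 0.022), in miR-143 by 2.17 (SE 0.50, adjusted p = 0.0044) and in miR-126 by 1.87 (SE 0.45, adjusted p = 0.0066). These were lower in TS: miR-31 (−1.56, SE 0.38), miR-20a (−1.38, SE 0.24), miR-205 (−1.38, SE 0.43), miR-222 (−1.33, SE 0.36), miR-31* (−1.33, SE 0.23), miR-17 (−1.32, SE 0.23), miR-106a (−1.29, SE 0.23) and miR-34a (−1.23, SE 0.30). The TS means behind the first and last of these were 10.76 ± 2.17 for miR-451 and 9.89 ± 0.65 for miR-34a (SD, n = 4), against 7.84 ± 0.19 and 11.10 ± 0.41 in TNE (n = 11). Each of them lay on the stated side of the TNE mean of its batch in 4 of 4 TS arrays.

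In all, 81 of 568 probes passed, 26 higher and 55 lower in TS, and 159 had an unadjusted p under 0.05. miR-665 (1.43, SE 0.29), miR-483-5p (1.33, SE 0.34), miR-658 (1.24, SE 0.32), miR-671-5p (1.23, SE 0.24), miR-503 (1.20, SE 0.36), miR-583 (1.13, SE 0.25), miR-518c* (1.04, SE 0.16), miR-185 (0.94, SE 0.23) and miR-572 (0.92, SE 0.27) were higher. miR-668 (−1.47, SE 0.41), miR-130a (−1.17, SE 0.23), miR-15b (−1.16, SE 0.20) and miR-212 (−1.10, SE 0.33) were lower. Plant probes were called higher at 27 (6.84%) and lower at 6 (1.52%) of 395, and viral probes at 8.53% and 4.65%. For human probes the shares were 4.58% and 9.68%, so calls upward were no more frequent among human probes than among these. Because TE and TS were set against the same TNE arrays, their results share chance values, and the overlap between them was not tested.

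Among the lists, 17-92 and its paralogs fell in 10 of 23 probes, over the list alone 10 lower and 1 higher (camera adjusted p = 0.000168), miR-23/miR-24/miR-27 in 5 of 7 (6 over the list alone; 0.00272) and miR-221/miR-222 in 2 of 3 (3 over the list alone; 0.0303). Camera also called the miR-143/miR-145 cluster (1 of 4 higher, 2 over the list alone; 0.0303), the erythroid list (1 of 4, 1 over the list alone; 0.0303), the muscle list (1 of 9, 2 over the list alone; 0.0303) and the miR-199/miR-214 cluster (0 of 6 on both; 0.0431). With an estimated correlation none held, with adjusted p = 0.249 for 17-92, miR-143/miR-145 and the erythroid list, 0.262 for miR-23/miR-24/miR-27, 0.272 for miR-221/miR-222 and muscle, and 0.375 for miR-199/miR-214. let-7i fell by 0.92 (SE 0.18), 1 of 3 let-7 probes that passed (5 over the list alone), and the miR-200 family had 0 of 9 on both counts. Camera called no other list. Fry called 6 of these 7, not miR-199/miR-214 (adjusted p = 0.0725), and, lower, miR-181 (2.8e-05), other epithelial (0.000763), miR-15/miR-16 and let-7 (0.0139 each) and miR-34/miR-449 (0.0434).

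The values rest on few arrays. Batch 1 holds 1 TS array, whose difference from the TNE mean of that batch was 0.08 for miR-451, 0.28 for miR-143, 0.33 for miR-126 and −0.28 for miR-31. Over the 3 TS arrays of batch 2 the differences were 4.04, 3.52, 3.00 and −1.84. All 3 lay on the early slide lot, while of the TNE arrays of that batch 1 lay on the early and 2 on the late lot. The fit had no term for slide lot, so a lot effect cannot be fully told apart from a TS difference in batch 2. Of the 81 called probes 79 and 81 had the same direction within batches 1 and 2. With donor as a fixed block 18 probes passed, and without TS replicate 1 or 2 there were 50 or 49; 10 of the 24 probes named above lost their call in at least 1 leave-out, miR-205 in 3 of 4 (highest adjusted p = 0.123) and miR-451 (0.085), miR-503 (0.201), miR-668 (0.134), miR-572 (0.124) and miR-212 (0.0903) in 2 of 4, and with the authors' matrix values 24 passed, 23 of them higher. Median scaling put the median difference of all probes at 0.39 and split 63 calls 57 higher to 6 lower. It turned the medians of the 17-92, let-7, 14q32, miR-15/miR-16, miR-29, miR-34/miR-449, miR-181, embryonic and prostate-cited lists above 0.

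No probe separated TS from TE. In limma's test 0 of 568 probes passed (smallest adjusted p = 0.529) and 10 had an unadjusted p under 0.05. miR-7 had the smallest p, with a log2 difference of −0.60 (SE 0.16, lower in 4 of 4 TS arrays). The next were miR-599 (0.34, SE 0.10), miR-490-3p (0.30, SE 0.11), miR-557 (0.58, SE 0.22), miR-744 (−0.28, SE 0.11), miR-548c-3p (−0.20, SE 0.08), miR-204 (−0.12, SE 0.06), miR-302c* (0.30, SE 0.14), miR-614 (−0.18, SE 0.08) and miR-493 (0.17, SE 0.08), none past the threshold. The 95% interval of the difference lay within ±1 on the log2 scale for 548 probes, and its median half-width was 0.205, and it lay within a 1.5-fold change either way for 468. These intervals describe intensities: 465 probes exceeded the 95th percentile of the plant probes on no TE array, so at most probes they exclude no difference in the miRNA itself.

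The let-7 family, miRNAs of differentiated cells, was the single list camera called between TS and TE, with a median of −0.10 over 15 probes, 0 of which passed on either count (camera adjusted p = 0.0367; adjusted p = 0.677 with an estimated correlation; fry adjusted p = 0.872). The embryonic stem cell clusters had a median of −0.01 over 11 probes and the miR-200 family 0.07 over 9, with no probe past the threshold in either, adjusted over all probes or over the list alone.

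Stromal cells differed from TNE in the miRNAs that separate mesenchymal from epithelial cells. miR-143 was higher in S (4.48, SE 1.06, adjusted p = 0.0123), at 13.00 ± 1.63 against 8.41 ± 0.34 (SD, n = 11 each). miR-199a-5p was higher by 3.87 (SE 0.55), miR-214 by 3.31 (SE 0.69), and miR-199a-3p/miR-199b-3p by 3.95 (SE 0.68) and 2.70 (SE 0.54) on its 2 probes, all mesenchymal miRNAs of the miR-199/miR-214 clusters. In TNE none of these 5 probes exceeded the 95th percentile of the plant probes on any of 11 arrays, so their sizes start from background. Lower in S were miR-141 (−4.25, SE 0.56, adjusted p = 2.21e-05), miR-200a (−3.69, SE 0.47), miR-200b (−3.66, SE 0.47), miR-200c (−3.41, SE 0.51) and miR-205 (−3.70, SE 0.68), all known from epithelial cells. Relative to the control of its batch, every S array was on the stated side of the TNE mean for these, except that miR-214 was higher in 10 of 11.

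In all, 22 of 568 probes passed, 9 higher and 13 lower, and 73 had an unadjusted p under 0.05. let-7i (1.27, SE 0.32), miR-155 (0.95, SE 0.27), miR-580 (0.68, SE 0.18) and miR-372 (0.43, SE 0.12) were the other higher probes. Within batches 5 and 6, S minus the control array was 1.33 and 1.60 for let-7i, 0.93 and 0.98 for miR-155, 0.26 and 0.24 for miR-580, and 0.20 and 0.033 for miR-372, with the last 2 far smaller within batches than in the fit. miR-429 (−1.80, SE 0.37), miR-31* (−1.65, SE 0.36), miR-182 (−1.52, SE 0.31), miR-378 (−1.30, SE 0.24), miR-183 (−1.13, SE 0.26), miR-203 (−1.09, SE 0.26) and miR-452 (−0.80, SE 0.22) were lower, as was miR-362-3p (−0.49, SE 0.13), which lay outside the naming rule and was chosen after its value was seen. For miR-182, miR-183, miR-203, miR-452, miR-580 and miR-372, no S or TNE array exceeded the 95th percentile of the plant probes. Within batches 5 and 6, miR-203 was −0.74 and −0.66 and miR-452 −0.40 and −0.83, and 7 and 4 of the 21 named probes lay further from the fitted value than the spread between replicates. The unadjusted mean of miR-580 was lower in S (8.38 against 8.73), while the control RNA's level at this probe fell by 0.88 from batches 1 to 3 to batches 5 and 6.

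The miR-200 family fell in 5 of 9 probes (camera adjusted p = 1.4e-09), the miR-199/miR-214 cluster rose in 4 of 6 (4.47e-09) and the other epithelial list fell in 5 of 10 (3.19e-08); adjusted over the list alone the counts were 5, 5 and 6. These 3 held with an estimated correlation, with adjusted p = 0.00353, 0.00345 and 0.000227. Camera called 5 further lists that did not: the 14q32 cluster, an imprinted miRNA cluster, with a median of 0.18 and 0 of 44 probes on both counts (0.00272; adjusted p = 0.176 with an estimated correlation); 17-92, median −0.29, 0 of 23 on both (0.00223; 0.206; fry adjusted p = 0.0604); prostate-cited, 3 of 19 lower on both (0.0258; 0.176); muscle, 1 of 9 higher on both (0.0343; 0.257); and miR-143/miR-145, 1 of 4, 3 over the list alone (0.038; 0.206). Within batches 5 and 6, the mean of S minus the control array was −1.64 and −1.91 as the miR-200 median, 3.36 and 2.61 as the miR-199/miR-214 median, and 5.10 and 4.28 for miR-143. In the miR-99/miR-100/miR-125 group miR-125b (3.01, SE 1.05) and miR-100 (2.42, SE 0.83) missed the threshold over all probes, and 2 of 10 probes passed over the list alone.

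S shared no batch with the other cell types, so these values are linked through the control RNA, 1 array in each batch; miR-155, miR-452 and miR-580 lost their calls in 5, 2 and 1 of 11 leave-outs. Median scaling put the median difference of all probes at 1.17 and called 352 higher and 6 lower, with miR-183, miR-452 and the medians of 17-92 and the prostate-cited list turned above 0, and let-7i was −0.21 in the authors' matrix values.

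**Figure D2:**
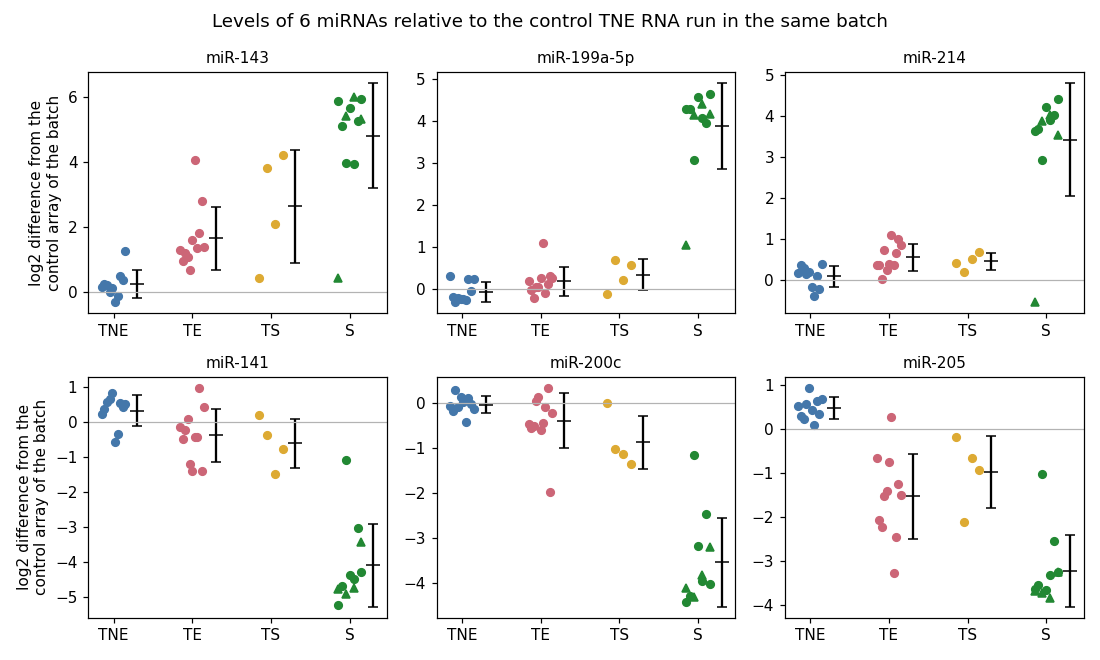
Log2 difference of each array from the control TNE array of its batch (vertical axes) for 6 miRNAs in 10 TNE, 11 TE, 4 TS and 11 S samples; points are arrays (in S, circles for batch 5 and triangles for batch 6), black bars are mean ± SD, and the control arrays are the grey line at 0. S arrays averaged 4.80 ± 1.61 for miR-143 and −4.10 ± 1.19 for miR-141. The lowest values in S were 0.42 for miR-143, 1.03 for miR-199a-5p and −0.56 for miR-214. They came from S replicate 10 of batch 6, the array whose brightest human probes were the weakest. An S array of batch 5 kept the most miR-141, miR-200c and miR-205.

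Against TE, stromal cells showed the same pair of lists and, in addition, higher miR-221. miR-221, in TE above the 95th percentile of the plant probes on 0 of 11 arrays, was higher in S (2.12, SE 0.31, adjusted p = 0.000138), and miR-222 was higher by 2.36 (SE 0.70, adjusted p = 0.055) without passing. miR-199a-5p was higher by 3.77 (SE 0.55), miR-199a-3p/miR-199b-3p by 3.74 (SE 0.68) and 2.54 (SE 0.55), miR-214 by 2.98 (SE 0.69), let-7i by 2.02 (SE 0.32) and miR-130a by 2.10 (SE 0.61), a call lost in 8 of 11 leave-outs (highest adjusted p = 0.0853). miR-141 (−3.72, SE 0.56), miR-200b (−3.24, SE 0.47), miR-200c (−3.14, SE 0.51) and miR-200a (−2.91, SE 0.47) were lower. miR-205 differed by −1.73 (SE 0.68, adjusted p = 0.146) and miR-143 by 3.28 (SE 1.06, adjusted p = 0.074).

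In all, 25 of 568 probes passed, 11 higher and 14 lower, and 108 had an unadjusted p under 0.05. miR-654-3p (1.11, SE 0.30), miR-155 (1.08, SE 0.27), miR-181b (0.79, SE 0.23) and miR-455-5p (0.71, SE 0.19) were also higher. miR-483-5p (−1.83, SE 0.52), miR-182 (−1.61, SE 0.31), miR-583 (−1.46, SE 0.42), miR-518f* (−1.38, SE 0.25), miR-198 (−1.29, SE 0.37), miR-625 (−1.13, SE 0.29), miR-183 (−1.10, SE 0.26) and miR-203 (−0.99, SE 0.26) were lower. For miR-455-5p, miR-182, miR-518f*, miR-625, miR-183 and miR-203, no S or TE array exceeded the 95th percentile of the plant probes. The lists miR-199/miR-214 (4 of 6 higher, 6 over the list alone; camera adjusted p = 1.34e-06), miR-200 (4 of 9 lower, 5 over the list alone; 1.34e-06) and other epithelial (3 of 10 lower, 5 over the list alone; 0.00166) passed and held with an estimated correlation (adjusted p = 0.0181, 0.023 and 0.0181). miR-221/miR-222 (1 of 3, 2 over the list alone; 0.0022) and 14q32 (1 of 44, 4 over the list alone; 0.00379) passed and did not hold (adjusted p = 0.0941 and 0.162 with an estimated correlation). Fry called the same 5 lists.

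Without S replicate 10, whose brightest human probes were the weakest, 61 probes passed, and without S replicate 4 there were 38. The probes miR-583, miR-483-5p, miR-181b, miR-198 and miR-203 lost their calls in 6, 5, 4, 4 and 1 of 11 leave-outs. With the authors' matrix values 51 passed, 6 higher and 45 lower, and under median scaling, which put the median difference of all probes at 0.80, the split was 22 to 10.

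Against TS, stromal cells were higher in miR-199a-5p (3.87, SE 0.65, adjusted p = 0.00142), miR-199a-3p/miR-199b-3p (3.65, SE 0.81, and 2.46, SE 0.65), let-7i (2.08, SE 0.38), miR-221 (1.63, SE 0.37) and miR-372 (0.53, SE 0.14). They were lower in miR-141 (−3.97, SE 0.66), miR-200a (−3.21, SE 0.56), miR-200b (−3.12, SE 0.56), miR-200c (−3.04, SE 0.61) and miR-518f* (−1.27, SE 0.29). The second miR-199a-3p/miR-199b-3p probe and miR-372 lost their calls in 8 of 11 leave-outs (highest adjusted p = 0.0854). For miR-372 and miR-518f*, no S or TS array exceeded the 95th percentile of the plant probes. These 11 probes were all that passed among 568, and 17.8% had an unadjusted p under 0.05. The lists miR-199/miR-214 (3 of 6 higher, 6 over the list alone; camera adjusted p = 5.36e-06), miR-200 (4 of 9 lower, 5 over the list alone; 5.36e-06) and other epithelial (0 of 10, 2 over the list alone; 0.00406) passed, each with adjusted p = 0.0288 with an estimated correlation. The lists 14q32 (0 of 44 on both; 0.0262) and miR-221/miR-222 (1 of 3 on both; 0.0431) passed and did not hold, both with adjusted p = 0.321 with an estimated correlation. Fry called these 5 and, higher, miR-15/miR-16 and miR-34/miR-449 (adjusted p = 0.0453 each). Without S replicate 10 or 4 there were 31 or 17 probes, the authors' matrix values split 25 calls 1 higher to 24 lower, and median scaling, which put the median difference of all probes at 1.04, set the other epithelial median at 0.18.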

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

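Of the tests in this part, 3 were chosen only after the result was seen: the correlation of the unlisted human probes with the plant probes, the calls made without 1 batch, and the share of S calls kept with the control array subtracted.

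Probes called higher in TE than in TNE form the first pattern, because 54 of the 395 plant miRNA probes, which have no target in human RNA, were called higher as well (13.7%, against 9.57% of human probes). Batch is argued against: of the probes called higher on the pairs of 2 batches, at least 95.5% were higher in the batch left out, whereas the 100% of the 54 probes that were higher in all 3 batches decides nothing, since these pairs made the call. Scaling stays open, since 98.1% kept the call under median scaling, which put the median difference of all probes at 0.29 and so could hardly end a call upward. Cross-hybridisation is a candidate explanation for unlisted probes such as miR-765 and miR-665: over the 10 pairs the mean difference of the 39 human probes called higher outside the fixed lists went with that of the plant probes (Pearson r = 0.853, p = 0.00364, adjusted p = 0.0133 over 11 relations; Spearman rho = 0.721, p = 0.0237; r = 0.855 without the 2 farthest pairs; permutation tests), and a change of these miRNAs in tumor cells stays open beside it. More long RNA in TE stays open too: U6-snRNA-1 (1.12, SE 0.30, 9 of 10 pairs) and SNORD3@ (0.98, SE 0.21, 10 of 10), the 2 of 12 small nuclear and nucleolar RNA probes called higher, went with the plant probes (r = 0.806, p = 0.00324, adjusted p = 0.0133; rho = 0.685, p = 0.0337; r = 0.797 without the 2 farthest pairs), but they were picked for their rise and 8 of the 12 lay below 0, SNORD13 at −0.34 and SNORD2 at −0.25.

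The second pattern is miR-451, miR-126, miR-143 and miR-142-3p higher in TE. Their mean difference did not go with that of the plant probes (r = 0.0751, p = 0.862, adjusted p = 0.862, with rho = −0.042, p = 0.918, and r = −0.468 without the 2 farthest pairs). Cross-hybridisation stays open, because a relation not seen over 10 pairs cannot exclude it. RNA of blood, vessel and smooth muscle cells in the TE samples is a candidate explanation: the 4 probes' differences had a median pairwise r of 0.632 over 10 pairs. Among the 6 relations only miR-126 with miR-143 passed adjustment (r = 0.894, p = 0.0023, adjusted p = 0.0133, with rho = 0.709, p = 0.0271), and it fell to r = 0.433 without the 2 farthest pairs. Without such pairs the others ran from r = −0.19 (miR-126 with miR-142-3p) to 0.81 (miR-451 with miR-142-3p), and miR-451 with miR-126 fell from 0.68 to 0.22. The erythroid miR-486-5p (0.10, SE 0.06, adjusted p = 0.254), the leukocyte miR-223 (0.11, SE 0.08, adjusted p = 0.356) and the muscle miR-133a (−0.0076, SE 0.06, adjusted p = 0.942) did not pass, so the share of such RNA and a change within tumor cells both stay open.

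The third pattern is the rise of calls in S comparisons when batch is left out and the replicate block kept, 230 probes against 22 for S versus TNE. Of those 230, 67.8% had a shift of the control RNA between batches with the same sign as the S difference, between the share foreseen if that shift were the cause and the share foreseen if not. With the control array subtracted and still no batch term, 211 probes were called, and 130 of the 230 (56.5%) stayed called in the same direction. Removing the shift did not end those calls, but that fit leaves out the error of the 1 control array subtracted in each batch. The 211 may therefore hold calls that rest on this error. For the other 100 the shift and the noise of a single control array cannot be told apart, because each batch holds 1 such array.

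Splits of the arrays were drawn to ask whether chance can be excluded. For TE versus TNE 1 of 100 label swaps within pairs, the real one, gave as many probes as were called (highest other 1), and for TS versus TNE 1 of 100 within batches gave 81 (highest other 37), so chance can be excluded for both counts. For S versus TE 1 of 100, the real one, gave 25 (highest other 14), so no other split drawn reached that count. For S versus TNE 2 of 100 gave 22 or more and another split reached 27, so such a count was rare among the splits. For S these splits test neither batch nor the error of the 1 control array in each batch, because S shared no batch with the other cell types. They therefore do not exclude that such error added to the counts of the S comparisons. For S versus TS 9 of 100 gave 11 or more, the highest other 65, so chance cannot be excluded for that count, and an other count several times the real one points to a structure of these samples, which was not tested. For TS versus TE the real count was 0 and all 100 gave as many, the highest other 13.

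A single sample stood apart from its group in 3 of 60 groups tested, about as many as chance gives. For miR-106a, 1 of 10 pairs had a TE minus TNE difference of −2.53, the next being −1.59, a gap of 0.520 of the range. For miR-668, 1 of 4 TS arrays was at 12.47 and the next at 10.08, a gap of 0.943 of the range. For miR-548c-3p, 1 of 4 TS arrays was at 7.65 and the next at 7.58, a gap of 0.906 of the range.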

How the results depend on the processing

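Mean pixel intensity, the plant probe background, the filter against plant probes and the removal of 2 weak S arrays were chosen after seeing the data. All 24 named probes of TE versus TNE kept direction and call under every alternative that tested them, and its count ran from 132 to 156 over the 10 left-out pairs and was 121 with no replicate block, 117 (88 higher, 29 lower) under median scaling and 132 (100 higher, 32 lower) with the authors' matrix; with the filter against plant probes it was 63, as only 84 probes were tested. For TS versus TNE that filter gave 53 of 85, the matrix 24, the replicate block as a fixed effect 18, no replicate block 79, and left-out TS arrays 49 to 89. Of the TE versus TNE calls under median scaling and with the matrix, 82 and 79 were also calls of the processing used above. For TS versus TNE these overlaps were 29 and 15, with 63 calls under median scaling. A similar count therefore did not mean the same probes. TS versus TE stayed at 0 in every alternative. For S versus TNE, S versus TE and S versus TS, counts were 230, 270 and 163 with no batch term and the replicate block kept, 211, about 2.0e2 and 103 with the control array subtracted, the replicate block kept and no batch term, and 20, 24 and 9 with no replicate block. Left-out S arrays gave 20 to 33, 20 to 61 and 9 to 31, replicate 10 alone giving the highest of each and replicate 4 giving 38 and 17 for S versus TE and S versus TS. Without the 2 weak S arrays the last 2 counts were 61 and 31. The matrix gave 51 for S versus TE and 25 for S versus TS, and median scaling 358 for S versus TNE. The count of list calls, 29, was 9 with the filter and 9 with the estimated correlation, and the control RNA's median SD of 0.193 was 0.428 under median scaling. Except where stated, the cause was not tested.

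Reversed in sign were, under median scaling, miR-34c-5p (0.023), let-7a* (0.011), miR-34a* (0.051), miR-17* (0.10), miR-30a* (0.10), miR-92a (0.026) and miR-181d (0.12) in TE versus TNE; miR-24-1*/miR-24-2* (0.13), miR-302c* (0.029), let-7a* (0.095), miR-656 (0.18) and miR-181d (0.12) in TS versus TNE; and miR-183 (0.14) and miR-452 (0.32) in S versus TNE. With the matrix, miR-222* (0.036), miR-17* (0.047) and miR-181d (0.24) reversed in TE versus TNE and let-7i (−0.21) in S versus TNE, and without a batch term miR-580 (−0.33) did. Those under median scaling lay below the median difference of all probes given with each comparison; for the others the cause was not tested. In leave-outs 14 of 24 named TS versus TNE probes, 18 of 21 for S versus TNE, 17 of 23 for S versus TE and 9 of 11 for S versus TS kept their call each time. Signal over background limits the dim probes: most human probes exceeded the plant probes on no array.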

Other observations

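Every value in this part was chosen after the data were seen, and no explanation of it was tested. The smallest adjusted p between TE and TNE belonged to miR-301a, a relative of miR-130a, which fell by 0.84 (SE 0.06, adjusted p = 1.25e-05) and was lower in 10 of 10 pairs. It lay outside the naming rule because its change was smaller than those of the probes named there.

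Probes for viral miRNAs were called as well: 13 (10.1%) were higher and 10 (7.75%) lower in TE than in TNE. In the 3 comparisons with S, 0 plant and 0 viral probes passed.

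On miR-451 the 4 TS arrays spread from 7.95 to 12.58, while the TNE arrays of the 10 pairs had a mean of 7.87 ± 0.19. S differed from TE by −1.63 for miR-126 (SE 0.64, adjusted p = 0.146), not past the threshold, and from TNE by −0.088 for miR-451 (SE 0.97, adjusted p = 0.97) and −0.25 for miR-126 (SE 0.64, adjusted p = 0.925).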
